A study of Mus musculus with 8 samples.

How the data were processed

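The authors' processed data were used: per-sample matrices of UMI counts per gene and cell from a droplet single-cell 3' library, deposited with their barcode and feature names. Per the file headers the counts are whole-number UMI counts from Cell Ranger, and the matrices also hold the counts of 12 cell tag features. The barcode files give one name per cell and the feature files give gene identifiers and symbols, as deposited by the authors. Per the labels each genotype was marked with 2 CellPlex tags, pooled and sequenced as 1 library on a NovaSeq. Per the submitters' processing notes reads were aligned to mm10 (GRCm38) with Cell Ranger 6.1.2, while the file headers name version 6.1.1. The gene annotation release behind the counts is not given in the sources used here, nor is the rule by which cells were assigned to tags. Raw reads were not used here.

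Each cell's own tag held 92.9% to 95.0% of its tag UMIs per sample. Matrices were read in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, 19377 of 19724. Tag features were left out of all gene tests, and symbols that occur more than once were told apart by gene identifier. Coordinates came from GENCODE M21.

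Counts of each cell were scaled to 10000 and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (leidenalg 0.10.2) were used, with umap-learn 0.5.12 and matplotlib 3.10.9 for drawing. A cluster was named for the class with the most markers at 1.1 times the level of the other cells and at least 10 CPM. At least 3 such markers and no tie were required. It was named proliferating-like when at least 5 proliferation markers had 1.5 times that level. A cluster whose median cell held under 1/3 of its sample's median UMIs stayed unnamed, which was so for cluster 6 (0.176) despite 8 basal markers. The markers were fixed beforehand, and these naming thresholds were set after the clusters had been seen. Clusters 0, 2 and 7 were named basal-like, 1 suprabasal-like, 4 and 5 proliferating-like, and 3 and 6 were left unnamed. Phase scores used the S and G2M lists on cells thinned to 4000 UMIs, with shallower cells left out, and were repeated without thinning. Scrublet was run per sample through scanpy and marked 0.201% of cells, so its calls were used only as an alternative. No cell had another tag above its own, so doublets of 2 tags may have been removed upstream, a step not given in the sources used here. Chromosome doses per cell used only cells with at least 1500 UMIs in the genes used. Background RNA was not removed and may move between the pooled groups.

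For tests the counts of all cells of a sample were summed. Genes were kept by filterByExpr (minimum count 10), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in one fit of 4 groups with 2 samples each. The 6 comparisons of the 4 groups were all tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes and an absolute log2 fold change of at least 1. The common biological coefficient of variation was 1.47%. The counts of the paired samples spread more than sampling alone would give, with chi-square per degree of freedom of 1.33 in WT, 1.48 in PC, 1.49 in PN and 1.46 in PCN. Classes were tested in the same way in samples with at least 50 cells of the class, and an interaction of genotype with class was tested between suprabasal-like and basal-like cells, a test added after the class results had been seen. Cell shares were tested with edgeR on cell counts per sample. Intervals of shares are exact binomial.

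There were 26 gene lists, written from general knowledge before the data were examined. They cover the edited genes, p53 and Notch targets, the cell cycle, keratinocyte and columnar differentiation, signalling, inflammation, antigen presentation, stress, metabolism and markers of other cell types. Of these 24 could be tested on voom values with camera at its preset correlation of 0.01, with its estimated correlation, and with fry. With the preset correlation 73 of 144 tests were called, with an estimated correlation none was (lowest adjusted p = 0.146), and fry called 123. Fibroblast markers had no tested gene (highest mean 0.0573 CPM), and of endothelial markers only Pecam1 was tested. Columnar, checkpoint and immune lists were tested and are drawn or described by single genes only.

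Genes named in the report were the edited genes, a fixed set (Ccl2, Cd274, Mki67, Krt5, Krt14, Krt13, Krt4, Trp63, Sox2, Cdkn1a, Cdkn2b, Hes1 and Vim), the 6 highest and 6 lowest fold changes among called genes of at least 50 CPM, and the 2 to 4 most changed called members of at least 10 CPM from each list described, leaving out unnamed, mitochondrial and ribosomal protein genes. Exceptions are Col1a1, Col1a2, Ptprc and Lyz2, given as markers of other cells, and Pecam1, given as the one tested endothelial marker. Further exceptions are Sel1l and Zc3h14, which bound the part of chromosome 12, and Nfkbia, given for its place on chromosome 12. Hoxc6, Hoxc5, Hoxc4, Hoxb2, Id2 and Wnt6 were picked after their values had been seen.

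The gene tests after the low count filter were tested on simulated data. In these, 50 genes per fold, each with a mean of at least 5 CPM, were changed by a known amount. The tests called none of the genes changed 1.5-fold, 98% to 100% of those changed 2.5-fold and every gene changed 4-fold or 8-fold. They also called 1 to 4 of 12686 unchanged genes. The simulated spread was that between the paired samples, so a spread between cultures was not covered. Most calls in the data lay under 5 CPM in the higher group, and these rates do not describe them. Chance overlap between comparisons that share WT was taken from independent lists of the same sizes. Overlaps and covariances of 40 simulated data sets without change were set beside it. Alternatives set beforehand were the DESeq2 1.42.0 Wald test, DESeq2-style size factors, library totals alone, no low count filter, a mean of at least 10 CPM, adjusted p alone, glmTreat, only the 4 samples compared, a replicate block, equal cells and depth, all barcodes, a stricter cell filter (1000 genes, 10% mitochondrial), Scrublet calls left out, clustering at resolutions 0.3 and 1.0 or without cell cycle genes, phases without thinning, and each sample left out in turn. Chosen after seeing the data were the highest doublet scores left out, the shallow mitochondrial cluster left out, suprabasal genes not used to cluster, and chromosome 12 genes left out. Some per-chromosome and single-gene checks were also chosen after seeing the data.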

Results

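Single-cell transcriptomes were collected from mouse esophageal organoids 7 days after seeding. Organoids are cultures in which epithelial cells grow into small layered bodies. There were 4 labelled genotypes with 2 samples each: wild type (WT), and organoids labelled as knockouts of Trp53 and Cdkn2a (PC), of Trp53 and Notch1 (PN), and of all 3 genes (PCN). After filtering, 19377 cells remained, with 2424 and 2406 cells in the WT samples, 2547 and 2291 in PC, 2547 and 3028 in PN, and 2212 and 1922 in PCN. The kept cells held 32840556 and 31445892 UMIs in gene features for WT, 38213104 and 34188268 for PC, 30929860 and 36228913 for PN, and 24453135 and 21655042 for PCN. The median cell held 11458 UMIs in WT, 12994 in PC, 10028 in PN and 9441 in PCN, and the median mitochondrial share was 2.03%, 2.07%, 2.43% and 2.87%. Levels (CPM) are UMI counts of the summed cells scaled to the same total per sample, given as mean ± SD with n = 2 samples per group, and log2 fold changes carry a standard error (SE). The 2 samples of a group differ by their cell tag, and separate cultures are not named for them, so every p-value measures only the spread between these samples, which may be technical. Genes are said to rise or fall only when called by the edgeR quasi-likelihood test, at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1.

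The edited genes were read first in every sample, since they show how far each label is borne out in the RNA. Trp53, the gene of the p53 tumour suppressor (chromosome 11: 69580359 to 69591873, GRCm38), stood at 56.2 and 56.0 CPM in the WT samples, 4.40 and 3.22 in PC, 6.11 and 5.58 in PN, and 7.85 and 7.07 in PCN. It fell 15.7-fold in PC (log2 −3.98 ± 0.069 SE), 10.4-fold in PN (−3.38 ± 0.06) and 8.66-fold in PCN (−3.11 ± 0.07), all against WT (edgeR, Benjamini-Hochberg adjusted p = 1.2e-47, 5.95e-46 and 2.32e-43). Cdkn2a, which encodes inhibitors of the cell cycle (chromosome 4: 89274471 to 89294653), had more RNA than in WT in every knockout-labelled group. It stood at 22.2 and 20.6 CPM in WT, 74.6 and 74.2 in PC, 57.7 and 57.9 in PN, and 216 and 222 in PCN. It thus rose 3.22-fold in PC (log2 1.69 ± 0.04) and 8.84-fold in PCN (3.14 ± 0.04), the 2 groups labelled as its knockouts, and 2.49-fold in PN (1.32 ± 0.04), which is not labelled so (edgeR, Benjamini-Hochberg adjusted p = 1.99e-41, 6.95e-59 and 5.03e-35). Notch1, a receptor that drives differentiation in this epithelium (chromosome 2: 26457903 to 26516663), stood at 34.0 and 30.1 CPM in WT, 18.4 and 17.99 in PC, 21.1 and 20.5 in PN, and 14.2 and 17.2 in PCN. It fell 2.37-fold in PCN against WT (log2 −1.25 ± 0.07; edgeR, Benjamini-Hochberg adjusted p = 1.37e-19). Its log2 value was −0.74 ± 0.06 in PN and −0.92 ± 0.06 in PC, neither of which passed the minimum of 1, although PC is not labelled as a Notch1 knockout. Without WT replicate 2 the PC value was −1.01 and passed. Reads come from the 3' end of each transcript, so RNA outside the edited part neither checks nor excludes an edit, and the groups are called by their labels throughout.

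**Figure D1:**
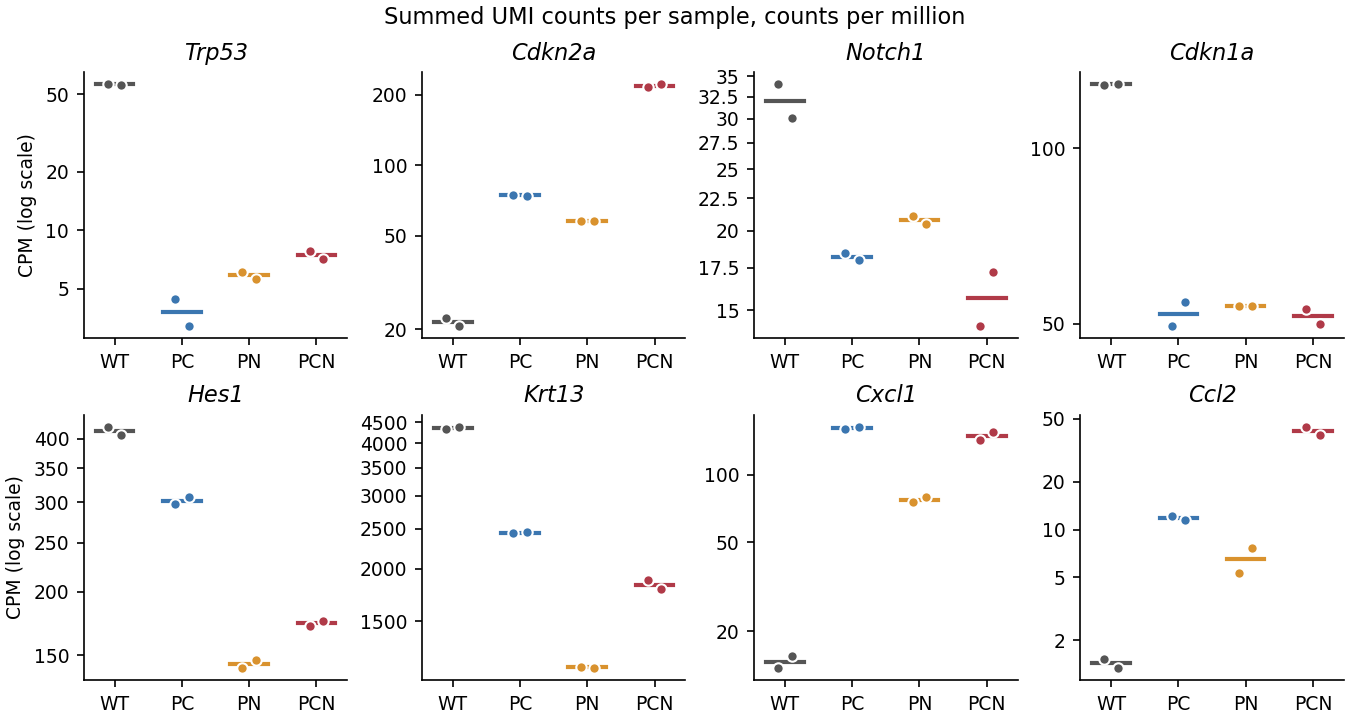
Levels (CPM, log axis) of 8 genes in the labelled WT, PC, PN and PCN organoids; each point is 1 sample and each line the mean of 2. Trp53 is low in every knockout-labelled sample, whereas Cdkn2a is highest in the samples labelled as lacking it.

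The comparison of PC-labelled with WT organoids asks what changes when p53 and Cdkn2a are both targeted. Of 29 measured p53 target genes, 5 fell and 24 did not pass (camera adjusted p = 5.98e-09; adjusted p = 0.146 with an estimated correlation). Cdkn1a, the cell cycle inhibitor that p53 induces, fell from 129 to 52.1 ± 3.49 CPM (2.67-fold, log2 −1.41 ± 0.03), and Ccng1, another p53 target, fell from 32.0 to 13.97 CPM (−1.30 ± 0.05). Cxcl1, a chemokine gene whose product attracts neutrophils, rose from 14.6 ± 1.26 to 162 ± 3.27 CPM (10.3-fold, log2 3.37 ± 0.05), and Ccl2, which attracts monocytes, from 1.43 ± 0.132 to 11.8 ± 0.557 CPM (7.64-fold, 2.93 ± 0.19). Among 30 NF-kB target and chemokine genes 12 rose, 1 fell and 17 did not pass (camera adjusted p = 6.36e-10; adjusted p = 0.146 with an estimated correlation). The member that fell was Il33, an epithelial alarmin, from 32.9 to 8.23 ± 1.23 CPM (4.33-fold, log2 −2.12 ± 0.07). The genes of proliferating cells were higher as sets, at a mean log2 of 0.50 for 43 S phase genes and 0.44 for 54 G2M genes, while each member stayed under the fold minimum (camera adjusted p = 1.07e-21 and 1.1e-27; adjusted p = 0.146 and 0.161 with an estimated correlation). Mki67, a marker of dividing cells, stood at 125 against 73.2 CPM (log2 0.66 ± 0.03, not passing).

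Differentiation genes moved in both directions in these PC-labelled organoids. Of 24 suprabasal and cornified keratinocyte genes 1 rose, 2 fell and 21 did not pass; adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 2.82e-05; adjusted p = 0.146 with an estimated correlation). Krtdap, a gene of differentiating keratinocytes, rose from 447 to 1165 CPM (2.41-fold, log2 1.27 ± 0.09), and Ecm1, an extracellular matrix gene of upper layers, fell from 136 CPM (log2 −1.89 ± 0.12). Krt13, the keratin of the suprabasal esophagus, had a log2 value of −0.94 and Krt4, its partner, of −0.26, neither passing. The basal keratin Krt5 stood at −0.09, or 0.02 when scaled by library totals alone, and Krt14 at 0.42. Outside the lists Fetub, a protease inhibitor gene, rose 5.09-fold (log2 2.35 ± 0.04), Igfbp2, an insulin-like growth factor binding protein gene, 2.87-fold, and Mt3, a metallothionein gene, 2.85-fold, while Gstm2, a glutathione transferase gene, fell 4.68-fold (log2 −2.23 ± 0.04) and Upk3bl, a uroplakin-like gene, 3.21-fold. In all, 650 of 12886 genes were called (324 higher, 326 lower), of which 30 reached 50 CPM in the higher group and 493 stayed under 5 CPM there (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, log2 of at least 1). Scaled by library totals alone the median log2 was 0.11 in this comparison, and the called split went from 49.8% to 59.1% higher.

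The comparison of PN-labelled with WT organoids asks how targeting Notch1, which pushes basal cells to differentiate, acts together with targeting Trp53. Hes1, a direct Notch target, fell from 415 ± 11.3 to 144 ± 3.56 CPM (3.12-fold, log2 −1.64 ± 0.02), and Nrarp, a feedback inhibitor of Notch, from 36.2 to 12.7 CPM (3.11-fold, −1.64 ± 0.07). Among 6 measured Notch target genes 2 fell and 4 did not pass (camera adjusted p = 0.0215; adjusted p = 0.185 with an estimated correlation). Krt13 fell from 4361 ± 42.7 to 1161 ± 5.70 CPM (4.07-fold, log2 −2.03 ± 0.02) and Krt4 from 1460.1 to 619 CPM (2.56-fold, −1.35 ± 0.02). Of the 24 suprabasal genes 8 fell and 16 did not pass, with 9 lower when adjusted over the list alone (camera adjusted p = 6.77e-09; adjusted p = 0.146 with an estimated correlation). Krt15, a keratin of basal progenitors, rose from 265 ± 23.3 to 773 CPM (2.69-fold, log2 1.43 ± 0.06), whereas Trp63, the transcription factor of basal cells, had a log2 value of 0.67 and did not pass.

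In the same comparison the p53 target Cdkn1a fell 2.59-fold (log2 −1.38 ± 0.03), and of the 29 targets 5 fell, 1 rose and 23 did not pass (camera adjusted p = 3.16e-06; adjusted p = 0.146 with an estimated correlation). Of 30 NF-kB genes 10 rose, 2 fell and 18 did not pass (camera adjusted p = 0.000523; adjusted p = 0.187 with an estimated correlation). Cxcl1 rose 4.93-fold (log2 2.30 ± 0.05) and Cxcl2, a related chemokine gene, 2.75-fold, while Il33 fell 11.3-fold and Tnfaip2, a TNF-induced gene, 2.14-fold. Of 25 NRF2 target genes, which serve detoxification, 4 fell and 21 did not pass (camera adjusted p = 4.65e-19; adjusted p = 0.146 with an estimated correlation), among them the aldehyde dehydrogenase gene Aldh3a1 (2.85-fold, log2 −1.51 ± 0.03). Hpgd, which degrades prostaglandins, rose from 7.10 to 82.8 CPM (log2 3.43 ± 0.06), Gnai1, a G protein subunit gene, 6.09-fold and Id3, an inhibitor of differentiation factors, 3.13-fold, while Calcb, a calcitonin-related peptide gene, fell 5.46-fold. In all, 979 of 12886 genes were called (483 higher, 496 lower), 64 of them at 50 CPM or more and 687 under 5 CPM (edgeR, the same rule). Under library totals alone the median log2 was 0.14 instead of 0.020, and the split went from 49.3% to 59.0% higher.

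The comparison of PCN-labelled with WT organoids asks what the labelled loss of all 3 genes does. The chemokine gene Ccl2 rose to 42.1 ± 3.50 CPM (25.5-fold, log2 4.67 ± 0.16), Cxcl1 to 149 CPM (8.84-fold, 3.14 ± 0.05), Tnf, the cytokine gene upstream of NF-kB, from 0.605 to 14.01 CPM (19.8-fold, 4.31 ± 0.16) and Ccl20, a chemokine gene, from 0.356 to 13.2 CPM (31.99-fold, SE 0.44 on the log2 scale). Of the 30 genes 17 rose, 1 fell and 12 did not pass, with 18 higher when adjusted over the list alone (camera adjusted p = 4e-10; adjusted p = 0.146 with an estimated correlation). The 1 that fell was again Il33, from 32.9 ± 0.618 to 1.31 ± 0.297 CPM (29.1-fold, log2 −4.86 ± 0.12). It lies on chromosome 19, of which some of the deeper WT cells held more RNA. The median chromosome 19 dose of the deeper cells was 1.00 in WT and 0.973 in PCN, far too close to account for a fall of this size. Of 17 interferon-stimulated genes 7 rose, 1 fell and 9 did not pass (camera adjusted p = 0.00375; adjusted p = 0.166 with an estimated correlation). Irf1, an interferon-induced transcription factor gene, rose from 10.4 to 42.0 CPM (3.50-fold, log2 1.81 ± 0.06), while Bst2, an antiviral membrane protein gene, fell 4.25-fold. Of markers of other cell types, Col1a1, a fibroblast collagen gene, stood at 0.0217 CPM in PCN. Cd68, a lysosomal gene used as a macrophage marker, fell from 32.0 to 15.2 CPM (2.43-fold), and S100a9, listed with immune cells but also made by keratinocytes, from 38.5 to 7.63 CPM (5.78-fold).

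In the PCN-labelled organoids Hes1 fell to 174 ± 2.84 CPM (2.76-fold, log2 −1.47 ± 0.02) and Nrarp 2.47-fold, and of 6 Notch targets 3 fell and 3 did not pass (camera adjusted p = 0.00868; adjusted p = 0.166 with an estimated correlation). Krt13 fell to 1836 ± 66.8 CPM (2.74-fold, log2 −1.46 ± 0.02) and Krt4 to 589.6 CPM (2.86-fold, −1.52 ± 0.02), and Tgm1, the enzyme that crosslinks the cornified envelope, from 47.9 to 14.1 CPM (3.92-fold, −1.97 ± 0.06). Of 24 suprabasal genes 7 fell, 1 rose and 16 did not pass, with 8 lower when adjusted over the list alone (camera adjusted p = 6.74e-07; adjusted p = 0.146 with an estimated correlation). Krt15 rose to 1446 ± 12.5 CPM (4.72-fold, log2 2.24 ± 0.06). Trp63 stood at a log2 value of 0.59, Sox2, a stem cell factor of the esophagus, at −0.06, or 0.14 under library totals, and Krt5 at −0.31, none passing. The 17 basal keratinocyte genes included 1 that rose and 16 that did not pass (camera adjusted p = 0.930), and their median log2 of −0.06 and test direction were down although their mean was 0.07.

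Among p53 targets Cdkn1a fell 2.88-fold (log2 −1.52 ± 0.04), and of 29 genes 5 fell, 2 rose and 22 did not pass (camera adjusted p = 0.000685; adjusted p = 0.146 with an estimated correlation). The growth factor binding protein gene Igfbp4 rose from 4.41 ± 0.245 to 116 ± 1.02 CPM (22.7-fold, log2 4.50 ± 0.06), Cxcl2 8.30-fold and Id3 5.57-fold, while Areg, a ligand of the EGF receptor, fell from 189 to 19.4 CPM (11.2-fold, −3.48 ± 0.05), Upk3bl 9.73-fold, and the simple epithelium keratin Krt19 8.46-fold (−3.08 ± 0.05). Of 25 NRF2 targets 10 fell and 15 did not pass (camera adjusted p = 4.33e-17; adjusted p = 0.146 with an estimated correlation). They included Aldh3a1 (3.36-fold, log2 −1.75 ± 0.03) and the glutathione transferase genes Gsta1 (4.93-fold), whose near copies may share its reads, and Gsta4 (2.54-fold). In all, 1490 of 12886 genes were called (671 higher, 819 lower), 150 of them at 50 CPM or more and 888 under 5 CPM (edgeR, the same rule). Library totals alone gave 1566 (988 higher, 578 lower) with a median log2 of 0.23 instead of 0.021, so the split went from 45.0% to 63.1% higher, and the mean of 28 oxidative phosphorylation genes from −0.15 to 0.05.

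Among chromosome 12 genes with a mean of at least 10 CPM over the 2 groups compared, 213 of 464 tested in PCN against WT, most were lower in the PCN-labelled organoids. Their median log2 against WT was −0.77 (82.6% lower), against −0.03 in PC and −0.04 in PN. The shift held for 156 genes up to Sel1l, a gene of protein quality control (start 91806043), with a median of −0.89, and not for 57 genes from Zc3h14, an RNA-binding protein gene (start 98746964), with 0.07. Over all tested genes chromosome 12 carried 3.601% of tested genes and 140 of the 819 lower calls (17.1%). Fos, an immediate early gene (2.67-fold lower, log2 −1.42 ± 0.02), Egln3, an oxygen sensor gene (2.46-fold lower), and Pdia6, a chaperone of the endoplasmic reticulum (log2 −1.31 ± 0.03), lie in this part, so their fall is not separable from the chromosome. The unfolded protein response list held 4 of 17 genes that fell and 13 that did not pass (camera adjusted p = 2.94e-05; adjusted p = 0.234 with an estimated correlation). Besides Pdia6 these included Trib3 (log2 −1.35 ± 0.11) and Asns (121 to 55.3 CPM, −1.33 ± 0.03), which are not on chromosome 12. The glycolysis and hypoxia list held 1 of 25 that fell, Egln3, with 24 not passing (camera adjusted p = 3.39e-12; adjusted p = 0.166 with an estimated correlation).

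**Figure D2:**
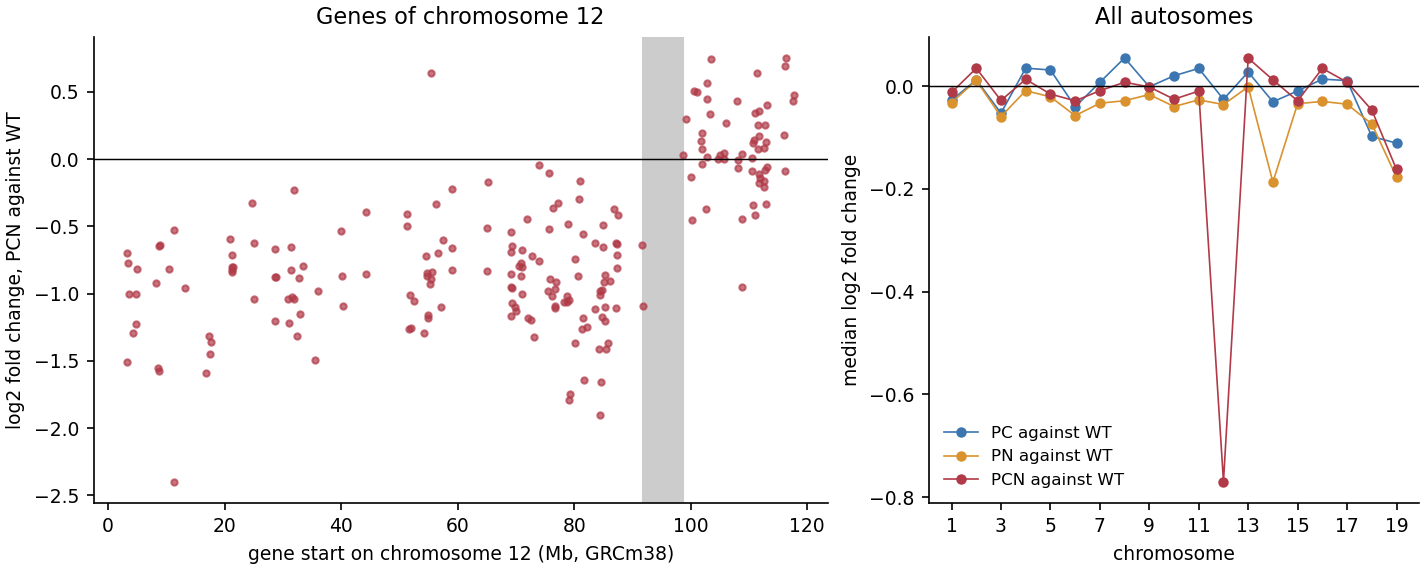
Left, log2 fold change of chromosome 12 genes in PCN-labelled against WT organoids over their start (Mb), each point 1 gene, with the gap between Sel1l and Zc3h14 in grey. Right, median log2 fold change per autosome for PC, PN and PCN against WT; chromosome 12 stands apart in PCN.

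The comparison of PCN with PC asks what labelled Notch1 loss adds. Cdkn2a RNA was above WT in both groups, which neither checks nor excludes the labelled edit. Krt15 rose from 186 to 1446 CPM (7.24-fold, log2 2.86 ± 0.07), Igfbp4 11.7-fold and Auts2, a chromatin regulator gene, 5.13-fold. Krt19 fell from 168 to 10.9 CPM (16.5-fold, log2 −4.05 ± 0.04), its partner Krt18 4.83-fold and Krt4 2.39-fold (−1.26 ± 0.02), whereas Krt13 had −0.51 and Hes1 −0.90, neither passing. The Notch target list held 2 genes that fell and 4 that did not pass (camera adjusted p = 0.0102; adjusted p = 0.166 with an estimated correlation). Suprabasal genes included 4 that fell, 1 that rose and 19 that did not pass (camera adjusted p = 0.000281; adjusted p = 0.161 with an estimated correlation), among them Krtdap (3.01-fold lower). Of 30 NF-kB genes 9 rose, 1 fell and 20 did not pass (camera adjusted p = 0.000513; adjusted p = 0.187 with an estimated correlation), with Ccl2 3.34-fold higher (log2 1.74 ± 0.10) and Tnf 2.63-fold higher. Trp53 had a log2 value of 0.86, which was 1.11 and passed without PC replicate 1, and Mki67 one of −0.05, or 0.05 under library totals. In all, 970 genes were called (475 higher, 495 lower), 79 of them at 50 CPM or more and 642 under 5 CPM, and chromosome 12 carried 103 of the lower calls, 20.8% (edgeR, the same rule). Under library totals the median log2 was 0.11 instead of 0.0069, and the split went from 49.0% to 59.5% higher.

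The comparison of PCN with PN asks what labelled Cdkn2a loss adds to Trp53 and Notch1. Cdkn2a RNA was 3.55-fold higher in PCN (log2 1.83 ± 0.03), which again neither checks nor excludes the edit. Ccl2 rose from 6.47 ± 1.66 to 42.1 CPM (6.04-fold, log2 2.59 ± 0.11), Tnf 6.42-fold, and Tnfaip2 3.34-fold (1.74 ± 0.03). Of the NF-kB genes 13 rose, 1 fell and 16 did not pass, with 14 higher when adjusted over the list alone (camera adjusted p = 6.1e-11; adjusted p = 0.146 with an estimated correlation). Interferon-stimulated genes included 4 that rose, each under 5 CPM, and 13 that did not pass (camera adjusted p = 0.000217; adjusted p = 0.150 with an estimated correlation). Ifitm3, an antiviral membrane protein gene outside that list, rose from 329 to 988 CPM (2.81-fold). Hoxc8, a gene of body axis patterning (chromosome 15: 102990607 to 102994111), fell from 57.6 ± 0.697 to 2.49 ± 0.522 CPM (24.3-fold, log2 −4.61 ± 0.08), Tmprss11a, an epithelial protease gene, 4.53-fold and H2-Ab1, a class II antigen gene, 2.93-fold. Hes1 had 0.17, Krt13 0.57 and Krt4 −0.16, none passing; 2 of the 24 suprabasal genes rose and 22 did not pass, with a median log2 of −0.04 and a mean of 0.16 (camera adjusted p = 0.772). Trp63 had −0.08, or 0.01 under library totals, and Mki67 −0.04, or 0.06. In all, 675 genes were called (298 higher, 377 lower), 37 of them at 50 CPM or more and 476 under 5 CPM, and chromosome 12 carried 96 of the lower calls, 25.5% (edgeR, the same rule). Under library totals the median log2 was 0.10 instead of 0.011, and the split went from 44.1% to 54.4% higher.

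The comparison of PN with PC sets the labelled Notch1 loss against the labelled Cdkn2a loss on a Trp53 background. Cdkn2a itself had a log2 value of −0.37, and Notch1 one of 0.18 (20.8 CPM in PN, 18.2 in PC). Notch1 RNA was thus not lower in the group labelled as its knockout. Krt15 rose 4.13-fold (log2 2.04 ± 0.06), Hpgd 2.92-fold and Sox4, a progenitor transcription factor gene, 2.24-fold. Hes1 fell 2.10-fold (−1.07 ± 0.02), Krt13 2.12-fold, Krt4 2.14-fold, and Krt19 5.21-fold (−2.38 ± 0.03). Of the Notch targets 2 fell and 4 did not pass (camera adjusted p = 0.0411; adjusted p = 0.209 with an estimated correlation), and of the suprabasal genes 6 fell and 18 did not pass (camera adjusted p = 4.81e-06; adjusted p = 0.146 with an estimated correlation). Among NF-kB genes 7 fell and 23 did not pass (camera adjusted p = 0.000281; adjusted p = 0.181 with an estimated correlation), with Cxcl1 2.10-fold, Cxcl2 2.34-fold and Tnfaip2 3.11-fold lower, while Ccl2 stood at −0.86, which became −1.17 and passed without PN replicate 2. In all, 484 genes were called (263 higher, 221 lower), 22 of them at 50 CPM or more and 370 under 5 CPM (edgeR, the same rule). The majority turned in other settings, with 137 higher and 168 lower by DESeq2 and 31 higher and 70 lower by glmTreat.

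**Figure D3:**
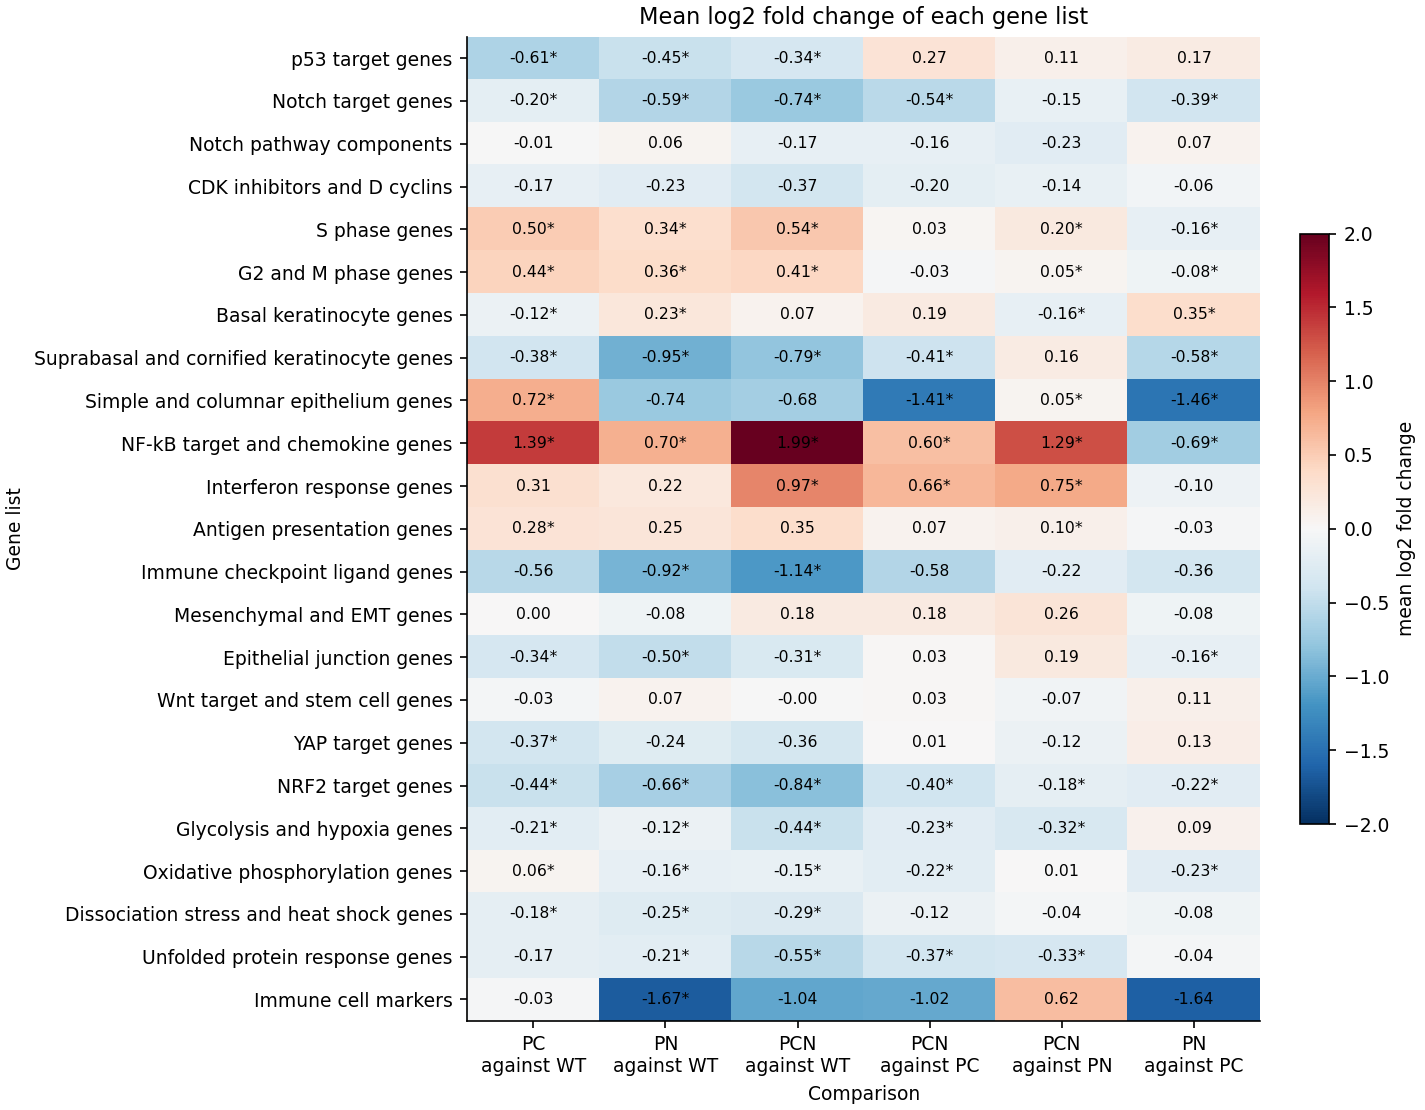
Mean log2 fold change of the members of 23 gene lists (rows) in the 6 comparisons of labelled genotypes (columns). Asterisks mark lists with camera adjusted p under 0.05 at the preset correlation, none of which holds with an estimated one; NF-kB genes have means above 0 in 5 comparisons and suprabasal genes below 0 in 5.

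Against WT the 43 S phase genes had a mean log2 of 0.34 in PN (camera adjusted p = 6.74e-11; adjusted p = 0.157 with an estimated correlation) and 0.54 in PCN with 1 that rose and 42 not passing (camera adjusted p = 1.46e-14; adjusted p = 0.146 with an estimated correlation). The 14 CDK inhibitor and cyclin genes included 3 that fell in PCN and 11 not passing (camera adjusted p = 0.154), among them Ccnd1, a G1 cyclin gene, from 302 to 164 CPM (2.12-fold). Of 23 junction genes 3 fell in PN and 20 did not pass (camera adjusted p = 0.000217; adjusted p = 0.176 with an estimated correlation), such as Cldn7, a tight junction gene. Of 10 mesenchymal genes 4 rose in PCN, 3 fell and 3 did not pass, with 5 higher over the list alone (camera adjusted p = 0.746; the median of 0.24 and mean of 0.18 were above 0 and the test pointed down). Snai2, an epithelial plasticity factor, rose from 33.5 to 89.2 CPM there (2.31-fold), and Vim stood at 0 CPM in every sample. Of 22 dissociation response genes 3 fell in PCN and 19 did not pass (camera adjusted p = 0.000629; adjusted p = 0.243 with an estimated correlation), Fos on chromosome 12 among them. Antigen presentation genes included 3 that rose in PCN and 12 not passing (camera adjusted p = 0.0926), with the proteasome subunit gene Psmb10 2.19-fold higher, and Cd274, the PD-L1 gene, stayed under 0.25 CPM in every group mean. Wnt target genes (camera adjusted p = 0.969) and Notch pathway components (camera adjusted p = 0.687) had no call as lists in PCN, and YAP targets had camera adjusted p = 0.0643. Oxidative phosphorylation genes had a mean log2 of −0.16 in PN (camera adjusted p = 9.91e-09; adjusted p = 0.166 with an estimated correlation).

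Cells were grouped into 8 clusters, named by keratinocyte and cell cycle markers, to ask how the make-up of the organoids differed. Suprabasal-like cells were 23.6% ± 0.535 (SD, n = 2) of WT, 15.2% ± 0.120 of PC, 3.15% ± 0.0719 of PN and 4.10% ± 0.346 of PCN cells, all in cluster 1. The log2 ratio to WT was −0.64 in PC, −2.90 in PN and −2.52 in PCN (adjusted p = 1.82e-06, 3.43e-09 and 7.98e-09, edgeR quasi-likelihood test on cell counts), and −0.70, −2.97 and −2.54 when suprabasal genes were not used to cluster. Krt13 and Krt4 are markers of this class, so their fall in all cells includes the fall in suprabasal-like cells. Proliferating-like cells were 23.2% ± 0.522 of WT, 49.97% ± 0.119 of PC, 40.1% ± 0.888 of PN and 48.5% ± 1.35 of PCN cells. Most were in cluster 4 in WT, PC and PN and in cluster 5 in PCN, which was nearly all PCN and was led by Igfbp4, Cdkn2a and Krt15. The log2 ratio to WT was 1.11, 0.79 and 1.06 (adjusted p = 4.67e-08, 3.14e-07 and 6.1e-08, edgeR), or 1.04, 0.76 and 0.82 without cell cycle genes. In that setting only the genes of the S and G2M lists were not used to cluster. Its proliferating-like clusters still had histone genes among their leading genes, so the shares are not free of the cell cycle.

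Phase scores on cells thinned to 4000 UMIs placed 25.1% of WT, 42.7% of PC, 35.9% of PN and 39.2% of PCN cells in G2M, and 25.03%, 42.8%, 37.0% and 38.8% without thinning. In S phase they placed 15.8%, 23.8%, 15.8% and 19.5%, and 17.7%, 25.1%, 16.2% and 20.5% without thinning; 24 and 26 shallow cells were left out in the WT samples, 16 and 5 in PC, 36 and 32 in PN, and 58 and 32 in PCN. Phase scores and cluster shares are relative to the other cells and read no rate of division. Basal-like cells were 48.3%, 18.2%, 49.2% and 44.9%, mostly cluster 0 in WT, cluster 2 in PC and PN, and cluster 7 in PCN; genes that differ between the groups lead these clusters, so the basal-like shares are not read as a difference. Cells of the unnamed clusters were 4.87% of WT, 16.7% of PC, 7.56% of PN and 2.57% of PCN. Cluster 3 held 215, 798, 370 and 45 of them, and cluster 6, shallow and mitochondrial (medians 1781 UMIs and 12.97%), held 20, 7, 53 and 63, most of the unnamed PCN cells. The Scrublet program marked 39 cells (0.201%) as doublets, and no cell had another tag above its own, so whether doublets were removed earlier or remain was not tested.

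**Figure D4:**
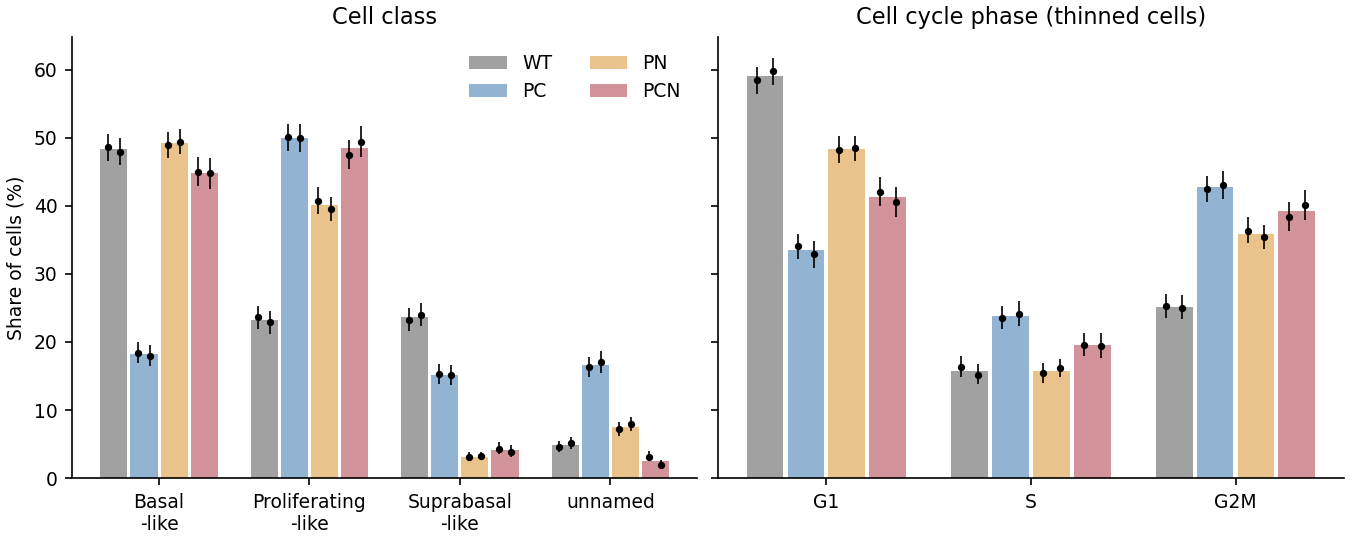
Percent of cells per class (left) and per thinned phase call (right) in the labelled WT, PC, PN and PCN organoids; bars are means of 2 samples, dots are samples, and whiskers are exact binomial 95% intervals. Suprabasal-like cells are fewest in PN and PCN, and proliferating-like cells are more frequent in the 3 knockout-labelled groups than in WT.

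Within classes the question was whether the gene changes remain when cells of one kind are compared. Hes1 fell in PN against WT in basal-like cells (log2 −1.73) and proliferating-like cells (−1.76), and stood at −0.71 in suprabasal-like cells without passing. In PCN against WT Hes1 fell by 1.497, 1.55 and 1.11 log2 in the basal-like, proliferating-like and suprabasal-like cells. Krt15 rose by 1.93, 2.37 and 2.92, Cxcl1 by 3.23, 2.95 and 3.02, and Cdkn2a by 3.32, 3.31 and 2.89 in the same order. The NF-kB list had mean log2 values of 2.22, 1.90 and 1.32 (camera adjusted p = 3.16e-12, 2.21e-12 and 0.000306 at the preset correlation; adjusted p = 0.113, 0.0533 and 0.292 with an estimated correlation). Different clusters stand for the basal-like and proliferating-like classes in WT and PCN, and the PCN clusters were led by Krt15, Cdkn2a and, in the basal-like one, Cxcl1. Basal-like cells were also mostly cluster 0 in WT and cluster 2 in PN, and Hes1 was among the leading genes of cluster 0. These within-class values are thus not free of how cells were grouped. For PCN against WT 1131 genes were called in basal-like cells, 1117 in proliferating-like and 669 in suprabasal-like cells (edgeR, the same rule within each class). Of the all-cell calls tested there, 820 of 1081, 924 of 1176 and 355 of 724 were called again. In suprabasal-like cells, which held the fewest UMIs, 138 of 412 were called again for PN against WT, with 82.5% of the same sign, and 47 of 182 for PN against PC, with 76.4%.

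The overlap of the 3 comparisons with WT asks whether the labelled genotypes share their changes. PN and PCN shared 303 higher and 378 lower genes, where independent lists of these sizes would share 25.2 and 31.5. PC and PN shared 229 and 222 (12.1 and 12.5 for independent lists), and PC and PCN 203 and 229 (16.9 and 20.7). Simulated data with no true change and the same shared controls gave at most 0.075 genes in any of these overlaps. Nearly no gene is called without a true change, so this count was low from the start and does not measure what shared controls add. Genes such as Cdkn1a, Trp53, Cxcl1 and Il33 were among 170 higher and 191 lower in all 3 groups. The covariance of log2 values was 0.348 for PC and PN, 0.380 for PC and PCN and 0.519 for PN and PCN, against 0.0322, 0.0324 and 0.0327 in the simulated data, which leaves 0.316, 0.348 and 0.486. The same 2 WT samples stand in each comparison and were not split, since each part would hold 1 sample, so part of the excess may come from shared controls.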

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

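The interaction test used here was not part of the fixed design: it was added after the gene and class results, though not its own, had been seen. It asked of each gene whether the effect of the labelled genotype in suprabasal-like cells differed from that in basal-like cells (edgeR quasi-likelihood, Benjamini-Hochberg), and 4 results for genes always named passed with a difference of at least 1 log2. Others passed by adjusted p with a smaller difference, such as Hes1 in PN against WT (0.98). Krt4 and Krt13 are among the markers that name the suprabasal-like class and Krt5 among the basal ones, so their effects within a class are partly set by how the classes are made. Basal-like cells were mostly cluster 0 in WT, cluster 2 in PN and cluster 7 in PCN, while suprabasal-like cells were all cluster 1. The basal-like effects of all 4 results, Cdkn1a among them, therefore compare different clusters.

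The class effects below come from the fits within each class and the differences from the interaction fit, so they do not subtract exactly. Cdkn1a in PN against WT had an effect of log2 −0.98 in basal-like and 0.13 in suprabasal-like cells, a difference of 1.07 ± 0.10 SE (adjusted p = 7.38e-12). Krt13 in PCN against WT had −0.94 in basal-like and 0.16 in suprabasal-like cells, a difference of 1.08 ± 0.04 (adjusted p = 2.44e-24). Krt5 in PCN against WT had −0.18 in basal-like and −1.32 in suprabasal-like cells, a difference of −1.17 ± 0.06 (adjusted p = 1.28e-19). Krt4 in PCN against WT had −1.55 in basal-like and 0.27 in suprabasal-like cells, a difference of 1.80 ± 0.05 (adjusted p = 9.33e-43).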

How the results depend on the processing

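Chosen only after results were seen were leaving out the highest 5% of doublet scores, leaving out the shallow mitochondrial cluster, clustering without suprabasal genes and leaving out chromosome 12 genes. Each group has 2 samples that differ by cell tag, so biological spread is hardly measured. Groups differ in depth, from 9441 UMIs per median cell in PCN to 12994 in PC. No list call holds with an estimated correlation.

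A mean of at least 10 CPM left 6400 genes to test and fewer calls: 88 in PC, 152 in PN and 337 in PCN against WT, 173 in PCN against PC, 118 in PCN against PN and 68 in PN against PC. Without a fold minimum more genes pass by construction, in the same order 5781, 6765, 7593, 6621, 5123 and 6273. Testing against the minimum itself (glmTreat) gave 227, 435, 803, 347, 202 and 101. The majority turned for PN against PC, with 28 higher and 40 lower at 10 CPM and 31 and 70 by glmTreat, and for PCN against PN, with 108 and 94 by glmTreat. It also turned without chromosome 12 in PC against WT (313 and 304), PCN against PC (471 and 392) and PCN against PN (294 and 281), without WT replicate 1 in PN against WT (482 and 474), and without a fold minimum in PCN against WT (3805 and 3788), PCN against PN (2688 and 2435) and PN against PC (3015 and 3258). Equal cells and depth, with fewer UMIs, gave 421 in PC and 616 in PN against WT and 438 in PCN against PN. DESeq2 called 305 in PN against PC (137 higher, 168 lower), and the cause was not tested. Leaving out 1 sample gave 639 to 700 calls in PC against WT, 947 to 1025 in PN, 1478 to 1588 in PCN, 909 to 1021 in PCN against PC, 627 to 699 in PCN against PN and 446 to 525 in PN against PC. Leaving out chromosome 12 left 1344 calls in PCN against WT, 863 against PC and 575 against PN.

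With the replicate number as a block, pairing first with first and second with second tags, the calls were 653, 972, 1495, 973, 672 and 488. Within basal-like cells resolution 1.0 gave 562 calls in PC against WT, 1105 in PCN against PC and 575 in PN against PC. At that resolution a cluster led by S phase genes was named basal-like. It held 125 WT, 634 PC, 319 PN and 16 PCN cells. The class therefore differs in make-up between the groups there, and these calls are not read as differences of basal cells. Overlaps without a fold minimum grew to 1536 higher and 1870 lower genes for PC and PN, 1731 and 2056 for PC and PCN, and 2323 and 2649 for PN and PCN.

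The basal-like share changed size or sign with settings. In PC against WT its log2 ratio was −1.41, and −0.46 without cell cycle genes and −0.87 without suprabasal genes. In the main setting a cluster led by a histone gene, with 798 PC cells, was unnamed. Without cell cycle genes a cluster led by the same gene, with 1649 PC cells, was named basal-like. Without suprabasal genes a cluster led by S phase genes, with 518 PC cells, was named basal-like. The log2 ratio of the basal-like share in PN against WT was 0.14 at resolution 0.3, −0.080 at 1.0, 0.13 without cell cycle genes, −0.17 without Scrublet doublets, 0.11 with the stricter filter, −0.073 without the highest doublet scores and 0.13 without suprabasal genes. In PCN against WT it was 0.16 at resolution 0.3, 0.041 without cell cycle genes, 0.20 without Scrublet doublets, 0.14 with the stricter filter, 0.039 without the highest scores, 0.15 without suprabasal genes, and −0.11 to −0.10 with 1 sample left out. In PCN against PN it was 0.025 at resolution 0.3, −0.015 at 1.0, 0.37 without Scrublet doublets, 0.035 with the stricter filter, 0.11 without the highest scores and 0.019 without suprabasal genes. Scrublet marked only 39 cells, but without them the cells were clustered anew. The unnamed cluster led by a histone gene then held 910 PN cells, against 370 in the main setting. The basal-like share thus depends on which clusters were named, and other causes were not tested.

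The proliferating-like share in PCN against PC had −0.42 at resolution 0.3, 0.13 at 1.0, −0.21 without cell cycle genes, −0.26 without Scrublet doublets and −0.12 without suprabasal genes. In PCN against PN it had −0.073 at resolution 0.3, 0.067 without cell cycle genes, 0.047 without Scrublet doublets and 0.092 without suprabasal genes, so neither difference is firm. The suprabasal-like share in PCN against PN was 0.25 with the stricter filter and 0.29 to 0.46 with 1 sample left out, and its call was lost in part of these. The S phase share in PN against WT was −0.12 without thinning, −0.031 without the highest doublet scores and −0.047 to 0.056 with 1 sample left out. The G2M share in PCN against PN was 0.068 without thinning and 0.10 to 0.16 with 1 sample left out, and in PCN against PC −0.15 to −0.093. The cause was not tested.

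Small values of single genes turned sign. Under library totals Krt5 in PC against WT was 0.020, Sox2 in PCN against WT 0.14, Mki67 in PCN against PC 0.052 and against PN 0.055, Trp63 in PCN against PN 0.0091, and the mean of oxidative phosphorylation genes in PCN against WT 0.054. In PN against PC Mki67 was 0.042 and Cdkn2b 0.040 at a mean of at least 10 CPM, Cdkn2b was 0.12 at equal depth and Mki67 0.0011 without the highest doublet scores. At equal depth Mki67 in PCN against PN was 0.039. With 1 sample left out Cdkn1a in PN against PC went from −0.023 to 0.10, Cdkn2b went from −0.039 to 0.017 and Mki67 from −0.037 to 0.014. Each of these genes stayed under the fold minimum in that comparison, and the cause was not tested. Over all settings 6171 values of named genes held their call and sign, 137 lost the call, 55 gained it and 15 turned sign.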

Other observations

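Chosen only after the values had been seen were the genes of the first paragraph, the chromosome counts of the second, the chromosome 12 checks on scaling, on few genes, on the whole chromosome and on a part of it, the Cdkn2a check on Trp53 loss alone, and the NF-kB checks on dissociation and on other cell types. A first check of chromosome 12 by 10 Mb stretches, 7 of 9 below −0.5, fell between its bounds and was replaced by those on the whole and on a part.

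Some single genes of body axis patterning differed between the labelled groups; they were picked by their values and no list of them was tested. Hoxc8 stood at 35.5 CPM in WT, 32.0 in PC, 57.6 in PN and 2.49 in PCN (16.3-fold lower in PCN than in WT, log2 −4.02 ± 0.09 SE, n = 2 per group), and its neighbour Hoxc6 at 13.97, 5.24, 7.49 and 1.38 CPM (log2 −3.53 ± 0.14 in PCN). Hoxc5 and Hoxc4 of the same cluster did not pass, at 30.6 and 85.6 CPM in PCN against 27.6 and 45.7 in WT. Hoxb2 rose from 26.6 CPM in WT to 59.9, 60.1 and 71.3 CPM. Id3, which blocks differentiation factors, rose against WT (47.6 CPM) in PC (107), PN (162) and PCN (307), while Id2, on the low part of chromosome 12, fell in PCN (log2 −1.04 ± 0.08). Wnt6, a Wnt ligand gene, fell from 16.8 CPM in WT to 7.35, 7.41 and 3.72 CPM.

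RNA per chromosome was scored in the deeper cells alone, those with at least 1500 UMIs in the genes used: 3018 of 4830 WT, 3801 of 4838 PC, 3035 of 5575 PN and 2258 of 4134 PCN cells. Of these, 1973 PN and 1620 PCN cells were proliferating-like, so the shares do not describe all cells. Chromosome 14 RNA was under 0.7 of the WT median in 21.03% ± 0.209 (SD, n = 2) of scored PN cells (26.2% of basal-like, 17.8% of proliferating-like), against 1.59% in WT, 4.15% in PC and 1.79% in PCN. Chromosome 19 RNA was over 1.3 of that median in 11.7% ± 0.183 of scored WT cells, against 1.42% in PC, 1.12% in PN and 1.17% in PCN. Doses from alternate genes of chromosome 14 correlated at 0.597 among PN and 0.115 among WT cells, but such values also stood at 0.600 in PN and 0.612 in PCN for chromosome 2, 0.527 in PC for chromosome 8 and 0.477 in WT for chromosome 3. The chromosome 14 doses of PN cells had a separate lower peak. The dose bins of width 0.1 that start at 0.5, 0.7 and 1 held 260, 198 and 667 PN cells. In WT the same bins held 13, 155 and 890 cells, without such a peak, and its cause was not tested. Chromosome 2 RNA was over 1.3 in 6.47% of PN and 5.32% of PCN cells against 2.02% in WT, chromosome 8 RNA in 7.09% of PC cells against 1.39%, and chromosome 13 RNA in 7.78% of PCN cells against 1.86%. Chromosome 18 RNA passed the same bound in 7.75% of WT cells, so such shares over 1.3 also arise without a labelled edit.

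Genes of chromosome 12 up to Sel1l were lower in PCN-labelled organoids, at 0.531 ± 0.00118 of the WT dose in the scored cells. Scaling does not account for this, as no other autosome had a median log2 beyond 0.16, nor do few genes, as 82.6% of the chromosome's 213 genes of at least 10 CPM were lower, nor a shift between classes, as the class nearest 0 had −0.73. The stretch nearest the end of the chromosome had 0.10, which argues against loss of the whole. The part was under 0.75 of the WT median in 93.3% of the 2258 scored PCN cells, which is consistent with loss of 1 copy of that part in most of these deeper cells; the other PCN cells were not scored. DNA was not analysed here, and whether the cells of a group descend from one cell stays open.

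Cdkn2a RNA was highest in PCN, which is labelled as its knockout. The lower of the other scalings gave log2 3.13, so scaling does not account for it. The lowest value within a class was log2 2.89, in suprabasal-like cells, which were cluster 1 in both groups. This argues against a shift between classes for those cells. The PCN basal-like and proliferating-like clusters were led by Cdkn2a among others, so their values cannot exclude such a shift. The smaller fold of PCN over PC and over PN was 2.75, although Trp53 RNA was low in all 3 groups. Trp53 loss alone may therefore not account for the high Cdkn2a RNA. Reads at the 3' end do not tell a working transcript from an edited one. The edited site and the protein were not analysed here.

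Of 30 NF-kB target and chemokine genes 17 rose in PCN against WT. Ccl2 and Tnf were highest in PCN, whereas Cxcl1 stood at 149 CPM in PCN and 162 in PC, and in PCN against PC 9 of the 30 rose, 1 fell and 20 did not pass (edgeR). The dissociation list had a mean log2 of −0.29, which argues only weakly against stress of dissociation. Most of its members did not pass, its test did not hold with an estimated correlation, and it holds Fos on the low part of chromosome 12. The highest of 4 immune and stromal markers (Col1a1, Col1a2, Ptprc and Lyz2) stood at 0.0217 CPM, which argues against such cells, although Cd68 stood at 15.2 CPM, below the 32.0 of WT. The lowest class mean was 1.32, in suprabasal-like cells, which argues against a shift between classes for those cells. The PCN basal-like cluster was led by Cxcl1 among others, so its class mean is not free of how cells were grouped. Chromosome 12 carries Nfkbia, an inhibitor of NF-kB. Nfkbia was not called lower, as Il33 was the only list member that fell in PCN against WT. A call needs a log2 fall of at least 1, while genes up to Sel1l had a median of −0.89. The missing call therefore cannot tell whether Nfkbia fell with that part. Whether the edits, the changes of chromosome 12 or the culture could raise these genes stays open.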
